A study of Homo sapiens with 6 samples.

How the data were processed

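The values used were CPM, read counts of each gene scaled by library size, computed by the authors before deposit. Reads were trimmed with Trim Galore and aligned with HISAT2, per the submitters' processing notes, which name both the human build hg38 and the mouse build mm10 and give no versions. The program that counted reads per gene, its gene annotation, its handling of strand and of reads shared between genes, and the way the library sizes were scaled are not given in the sources used here. Polyadenylated RNA was copied with random primers after DNase treatment, per the labels' protocols. The table held 52142 rows and 6 columns of CPM. Of these rows, 15200 carried no gene symbol and held 2.50% to 2.62% of a library's CPM, and 10 rows shared 5 symbols, so 36932 rows with a symbol of their own were kept.

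All values of each column were whole multiples of its smallest step, within 1e-06, so 1 read was worth the same CPM for every gene of a library. The planned design assumed read counts and gave a branch for normalized values. Because the deposited unit was CPM, that branch was used, and no test for read counts was run. Everything described from here on was computed from the deposited CPM. Genes with a mean of at least 1 CPM over the 6 libraries were tested, 13675 in all. Their log2(CPM + 1) values were fitted with limma-trend, with a robust spread shared by the 3 groups and no further covariates. Adding 1 CPM makes the log2 changes of weakly expressed genes smaller than their CPM ratios. The contrasts were the mean of both colonies minus control, each colony minus control, and colony 2 minus colony 1. Tests were two-sided, and a gene was called at a Benjamini-Hochberg adjusted p under 0.05. The labels do not say that the replicates were separate cultures, so the p-values measure only the spread between these libraries, which may be technical.

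The comparisons, the gene lists and the rule for naming genes were chosen before the data were examined. DDX18 is named first. Then come the 10 genes with the largest rise and the 10 with the largest fall among called genes of at least 20 CPM in the higher group, a regular gene symbol, and all 4 knockdown libraries on the same side of both controls. For each colony against control, and for colony 2 against colony 1, the 5 largest in each direction were taken by the same rule. From each gene list, the 2 called members with the largest change between knockdown and control were named, with the largest in the other direction where there was any. The results of 2 genes that this rule takes are not reported here. Other named genes are said to have been chosen after their values were seen.

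There were 27 lists of pathways and complexes. They covered ribosome biogenesis factors, RNA polymerase I machinery, cytosolic ribosomal proteins, other DEAD-box and DEAH-box helicases, R-loop processing factors, S phase and DNA replication, mitosis and G2/M, p53 pathway targets, DNA damage checkpoint and repair, interferon-stimulated genes, NF-kB and inflammatory cytokines, and ATF4 and amino acid stress response. They also covered endoplasmic reticulum chaperones, cytosolic heat shock proteins, NRF2 antioxidant genes, hypoxia and glycolysis, cholesterol biosynthesis, nuclear-encoded oxidative phosphorylation, mitochondrially encoded mRNAs, and extracellular matrix and mesenchymal genes. The remaining ones were YAP/TAZ targets, apoptosis regulators, MYC and nucleotide synthesis, pre-mRNA splicing factors, autophagy and lysosome, replication-dependent histones, and nuclear and small noncoding RNAs. A further 6 lists held markers of luminal breast epithelium, keratinocytes and basal epithelium, leukocytes, endothelium, fibroblasts and the embryonic kidney line HEK293. Each list was set against all other tested genes with limma's camera at an inter-gene correlation of 0.01. The p-values were adjusted over the 132 pairs of a list and a contrast by Benjamini-Hochberg. Members were also counted with the gene p-values adjusted over the list alone.

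Positions, transcript lengths and untranslated regions came from GENCODE release 29 on GRCh38, in which 36885 of 36937 distinct symbols matched 1 gene. For the overlap of the colonies, all 6 libraries were simulated 100 times without change, from each gene's spread within groups, with the 2 simulated controls shared. The tests were first run on simulated libraries with known changes in a set of genes, with 13600 to 13609 genes tested. For both colonies against control, 77.9%, 90.5% and 100% of genes changed by 1.5-fold, 2-fold and 4-fold were recovered, and 3.70% of all calls, those of a further set of slightly changed genes included, were false. The values for colony 1 were 68.1%, 96.6% and 95.7%, with 5.31% false calls, and those for colony 2 were 87.3%, 92.4% and 97.2%, with 2.80% false calls. For colony 2 against colony 1 they were 70.0%, 94.5% and 98.5%, with 3.43% false calls. R 4.3.3 with limma 3.58.1 and statmod 1.5.0, and Python 3.11.15 with NumPy 2.4.6 and matplotlib 3.10.9, were used.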

Results

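Messenger RNA was sequenced from MDA-MB-231 cells, a human line of triple negative breast cancer, which lacks the oestrogen and progesterone receptors and excess HER2. The aim stated for the series was to see the transcriptome after knockdown of DDX18, a DEAD-box RNA helicase of the nucleolus that takes part in making the large ribosomal subunit. There were 6 libraries in 3 groups of 2, namely control cells, a colony with DDX18 knocked down (colony 1) and another such colony (colony 2). The smallest CPM step of each library implied 9561782 and 9748680 reads for the controls, 9768470 and 9751200 for colony 1, and 11902437 and 8843847 for colony 2. A single read was thus worth 0.0815 to 0.108 CPM. Between 18049 and 19101 genes had a value above 0 in a library, and the 10 most abundant genes held 5.24% to 5.85% of its CPM. On the first principal component, with 66.5% of the variance, the controls lay at −34.5 and −32.1 and the knockdown libraries between 14.4 and 19.1. The second, with 12.3%, held colony 1 at −9.50 and −14.3 and colony 2 at 13.4 and 10.5.

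DDX18 mRNA was far lower in each of the 4 knockdown libraries than in the controls. The controls held 78.8 and 91.7 CPM, colony 1 held 17.6 and 14.0 CPM, and colony 2 held 14.7 and 15.1 CPM. The mean was 85.2 ± 9.14 CPM in control (SD, n = 2), 15.8 ± 2.52 CPM in colony 1 and 14.9 ± 0.331 CPM in colony 2. This left 18.6% ± 2.95 of the control level in colony 1 and 17.5% ± 0.388 in colony 2 (SD, n = 2). These values rest on 771 and 916 implied reads in the controls and 139 to 180 in the knockdown libraries. By limma the log2 change was −2.36 (SE 0.13, adjusted p = 1.6e-13) in colony 1 and −2.44 (SE 0.13, adjusted p = 8.7e-14) in colony 2. The difference between the colonies was −0.07 (adjusted p = 0.876). DDX18 lies on chromosome 2 of GRCh38 at 117814650 to 117832379 on the plus strand and is annotated as protein coding.

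**Figure D1:**
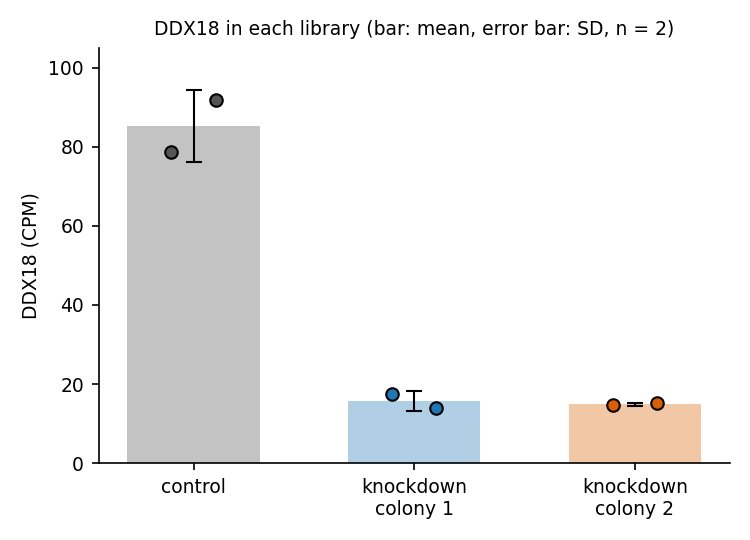
DDX18 expression in CPM for each library of the control, colony 1 and colony 2, with points for libraries and bars for the group mean and SD. The controls lay at 78.8 and 91.7 CPM and the 4 knockdown libraries between 14.0 and 17.6 CPM.

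The comparison of both knockdown colonies with control asked which transcripts change when DDX18 is low. Most genes of the mitosis and of the DNA replication lists rose and most of the cholesterol list and of the hypoxia and glycolysis list fell, in both colonies. Among genes of at least 20 CPM in the higher group, the largest rise was in LMNB1, which encodes lamin B1 of the nuclear lamina, from 27.3 ± 0.391 CPM in control to 156 ± 3.64 in colony 1 and 160 ± 9.95 in colony 2 (SD, n = 2), or 5.79-fold. The largest fall was in CPA4, a secreted carboxypeptidase, from 364 ± 8.19 CPM to 51.9 ± 4.11 in colony 1 and 48.1 ± 3.46 in colony 2, or 7.29-fold.

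By limma with Benjamini-Hochberg adjustment, 3171 genes were higher and 2944 lower in the knockdown, 44.7% of the 13675 tested. An absolute log2 change of at least 1 was reached by 210 of the higher and 228 of the lower genes. The error of this fit leaves out the spread between the colonies. With the 4 knockdown libraries fitted as 1 group, which takes in that spread, 2836 genes were higher and 2583 lower. LMNB1 had a log2 change of 2.49 (SE 0.07, adjusted p = 9.9e-20) and CPA4 one of −2.84 (SE 0.07, adjusted p = 1.2e-20). Next among the higher genes were PRDM8, a zinc finger protein of the PRDM family, at 1.97, SLC7A11, the cystine importer that feeds glutathione synthesis, at 1.93, and TMED5, a cargo receptor of the early secretory pathway, at 1.80. HS2ST1, a heparan sulfate sulfotransferase, changed by 1.76, STARD3NL, a late endosome protein, by 1.74, and TTPAL by 1.72. CPD, carboxypeptidase D, rose by 1.65, SCG2, the granin secretogranin II, by 1.64, and CAV2, caveolin 2, by 1.64. GTAAGCA, a 7-base sequence, stood in the 3′ untranslated region of 8 of these 10 higher genes, all but PRDM8 and SCG2, against 7.91% of the 12136 genes searched. This sequence was chosen after the values were seen, as the one most tied to these same changes, and the share is not matched for length of the region, which was 4928 nt or more in 5 of the 8.

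Besides DDX18, other lower genes were AQP3, a water and glycerol channel, at −2.24, VIPR1, a receptor for vasoactive intestinal peptide, at −1.95, and HSPB8, a small heat shock protein, at −1.89. MSMO1, an enzyme of cholesterol synthesis, changed by −1.76, COL4A6, a basement membrane collagen chain, by −1.71, and CFL2, the actin-severing cofilin 2, by −1.70. SYT12, a synaptotagmin, followed at −1.66 and ALPP, placental alkaline phosphatase, at −1.63. In CPM, AQP3 went from 50.4 to 9.47 and 10.2, VIPR1 from 63.0 to 15.3 and 15.9, and MSMO1 from 103 to 29.9 and 29.8. The adjusted p of the higher and lower genes named here was at most 6.9e-09, and all 4 knockdown libraries lay beyond both controls for each. VIPR1 and SLC7A11 have annotated antisense partners, and TMED5 overlaps CCDC18 on the opposite strand, so their values are uncertain where the counting ignored strand, as are those of THOC6, TOP1, KRT7, TYMS, PDIA6, PTPN14, NPC1 and CENPA, members of the gene lists that overlap other genes.

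Of the 44 mitosis and G2/M genes, 43 rose, and also 43 adjusted over the list alone, with a median log2 change of 0.66. Camera called the list (adjusted p = 2.5e-24, adjusted p = 0.81 with an estimated correlation). CENPA, the histone variant of centromeres, rose by 1.40 and CDC20, an activator of the anaphase-promoting complex, by 1.18. S phase and DNA replication genes followed, with 37 of 48 higher and 1 lower, and 37 and 2 adjusted over the list alone. Their median was 0.44 (camera adjusted p = 1.8e-09, adjusted p = 0.81 with an estimated correlation). RFC3, a subunit of the clamp loader, rose by 1.31 and POLA1, the catalytic subunit of DNA polymerase alpha, by 1.24, while GINS1 of the replicative helicase fell by 0.26.

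Genes of the DNA damage checkpoint and repair rose in 27 of 50 cases, likewise 27 adjusted over the list alone, with a median of 0.24 (camera adjusted p = 1.7e-04, adjusted p = 0.81 with an estimated correlation). NBN, which senses double-strand breaks, rose by 1.36 and BRCA2, a mediator of homologous recombination, by 0.94. Among R-loop processing factors, of which 15 of 38 also stand in other lists, 23 of 37 tested were higher and 3 lower, and 24 and 3 adjusted over the list alone. The median was 0.24 (camera adjusted p = 1.2e-03, adjusted p = 0.81 with an estimated correlation), with BRCA2 at 0.94, THOC6, a subunit of the THO mRNA export complex, at 0.74 and topoisomerase TOP1 at −0.68. Ribosome biogenesis factors, the class to which DDX18 belongs, were higher for 33 of 66 and lower for 1, and 34 and 1 adjusted over the list alone. Their median was 0.21 (camera adjusted p = 2.6e-04, adjusted p = 0.84 with an estimated correlation). RPF2, which acts in maturation of the large subunit, rose by 0.82 and the nucleolar phosphoprotein NOLC1 by 0.71, while GAR1, a protein of H/ACA particles, fell by 0.59. The other DEAD-box and DEAH-box helicases had 15 of 44 higher and 3 lower, and 15 and 2 adjusted over the list alone. Their median was 0.11 (camera adjusted p = 0.0497, adjusted p = 0.84 with an estimated correlation), with DDX39A at 0.71, DDX10 at 0.64 and DDX6 at −0.26.

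Cholesterol biosynthesis genes fell in 24 of 25 cases, also 24 adjusted over the list alone, with a median log2 change of −0.70 (camera adjusted p = 2.1e-15, adjusted p = 0.61 with an estimated correlation). MSMO1 fell by 1.76 and INSIG1, which restrains sterol sensing in the endoplasmic reticulum, by 1.49. Hypoxia and glycolysis genes were lower for 23 of 31 and higher for 1, and 28 and 1 adjusted over the list alone. Their median was −0.37 (camera adjusted p = 2.4e-09, adjusted p = 0.81 with an estimated correlation). ALDOC, a glycolytic aldolase, fell by 1.35 and NDRG1, a hypoxia-induced gene, by 0.85, while SLC2A1, the glucose transporter GLUT1, rose by 0.24. YAP/TAZ targets, genes switched on by these Hippo pathway coactivators, were lower for 13 of 22 and higher for 4, and 14 and 6 adjusted over the list alone. Their median was −0.38 (camera adjusted p = 8.0e-03, adjusted p = 0.81 with an estimated correlation), with NUAK2 at −1.28, CCN2 at −1.08 and PTPN14 at 0.85.

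Nuclear-encoded oxidative phosphorylation genes were lower for 20 of 37 and higher for 3, and 21 and 3 adjusted over the list alone, with a median of −0.19 (camera adjusted p = 3.7e-03, adjusted p = 0.81 with an estimated correlation). NDUFA8 and NDUFB5, subunits of complex I, changed by −1.15 and 0.30, and COX6A1 of complex IV by −0.67. The cytosolic ribosomal proteins had 22 of 76 lower and 5 higher, the same counts adjusted over the list alone, with a median of −0.07 (camera adjusted p = 0.023, adjusted p = 0.84 with an estimated correlation). RPS29 fell by 0.64, RPS15A by 0.52, and RPLP1 rose by 0.25. With colony 2 left out, RPS29 stood at 0.055 (adjusted p = 0.633), COX6A1 at 0.048 (adjusted p = 0.853) and the ribosomal protein median at 0.04996. With the 4 knockdown libraries fitted as 1 group, RPS29 (adjusted p = 0.470), COX6A1 (0.437), RPS15A (0.0882) and GINS1 (0.0507) were not called. Mitochondrial ribosomal RNA held 0.900% and 0.913% of CPM in the controls, 0.683% and 0.657% in colony 1, and 0.748% and 0.782% in colony 2, and mitochondrial mRNA 3.88% to 4.41% in the 6 libraries. Among markers of luminal breast epithelium, 14 of 23 were tested, 7 were lower and 3 higher, the same counts adjusted over the list alone, with a median of −0.30 (camera adjusted p = 0.020, adjusted p = 0.81 with an estimated correlation). AGR2, a secretory pathway disulfide isomerase, fell by 1.33 and keratin KRT7 by 0.87, while E-cadherin, CDH1, rose by 0.69. Fibroblast markers, 7 of 14 tested and 5 of 14 also in other lists, had 5 lower and 1 higher, likewise adjusted over the list alone, with a median of −0.55 (camera adjusted p = 0.032, adjusted p = 0.81 with an estimated correlation). The matrix genes LUM and COL1A1 fell by 1.68 and 1.38, and PDGFRB rose by 0.40.

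Camera did not call the other 20 lists, though each had called members. Endoplasmic reticulum chaperones (adjusted p = 0.055) had 9 of 21 lower and 3 higher, with the calreticulin gene CALR at −0.88, PDIA6 at −0.67 and PDIA4 at 0.39. Among NF-kB and inflammatory cytokine genes (adjusted p = 0.19), 8 of 24 were higher and 4 lower, with BIRC3 at 1.31, TRAF1 at 1.08 and IL24 at −0.73. NRF2 antioxidant genes (adjusted p = 0.23) had 9 of 21 higher and 4 lower, with SLC7A11 at 1.93 and haem oxygenase HMOX1 at −1.01. For extracellular matrix and mesenchymal genes (adjusted p = 0.24), 15 of 38 were lower and 9 higher, with COL1A1 at −1.38, COL1A2 at −1.26 and the integrin gene ITGA2 at 0.86. Replication-dependent histones (adjusted p = 0.24), whose mRNAs mostly lack a poly(A) tail, had 4 of 9 lower, led by H2BC21 at −0.97 and H2AC6 at −0.78. Nuclear and small noncoding RNAs (adjusted p = 0.34) had 5 of 14 higher and 2 lower, with SNHG1 at 0.81 and NEAT1, the scaffold of paraspeckles, at −0.67. Interferon-stimulated genes (adjusted p = 0.36) split into 12 higher and 17 lower of 44, with IFI6 at −1.45, OAS1 at −1.22 and HERC5 at 0.92. In the ATF4 and amino acid stress response (adjusted p = 0.38), 7 of 31 were higher and 9 lower, with SLC7A11 at 1.93 and ATF3 at −0.88. Pre-mRNA splicing factors (adjusted p = 0.43) had 12 of 44 higher and 7 lower, with U2AF1 at 0.54, SNRPF at 0.47 and SNRNP70 at −0.46. Cytosolic heat shock proteins (adjusted p = 0.45) had 7 of 15 lower and 2 higher, with CHORDC1 at 1.19 and HSPA4L at −0.89, and their median of 0.04 and mean of −0.08 differed in sign.

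RNA polymerase I machinery (adjusted p = 0.48) had 3 of 15 genes higher, led by the initiation factors RRN3 at 0.36 and UBTF at 0.28. Autophagy and lysosome genes (adjusted p = 0.53) had 9 of 33 higher and 11 lower, with NEU1 at −1.28, ATG9A at −0.81 and NPC1 at 0.59. For MYC and nucleotide synthesis (adjusted p = 0.55), 7 of 21 were higher and 4 lower, with PPAT of purine synthesis at −1.02 and thymidylate synthase TYMS at 0.76. Targets of the p53 pathway (adjusted p = 0.71) had 6 of 29 higher and 4 lower, with AEN at 0.94 and BTG2 at −0.73. Apoptosis regulators (adjusted p = 0.78) had 8 of 30 higher and 7 lower, with BIRC3 at 1.31. Mitochondrially encoded mRNAs (adjusted p = 0.87) had 4 of 13 higher and 2 lower, with MT-ND2 at 0.28 and MT-ND6 at −0.35. With colony 2 left out, MT-ND6 stood at −0.149 and was not called by limma (adjusted p = 0.0546). Of the 12 HEK293 markers (adjusted p = 0.23) only 2 were tested, and these were higher, GATA2 at 0.65 and ZIC2 at 0.56. Markers of keratinocytes and basal epithelium (adjusted p = 0.36), 4 of 14 tested, had TRIM29 at −1.44 and TP63 at 0.88 among 2 lower and 1 higher. Endothelial markers (adjusted p = 0.39), 4 of 10 tested, had 3 lower and 1 higher, with KDR at 1.41 and EGFL7 at −0.55. Leukocyte markers (adjusted p = 0.80), 4 of 15 tested, had 1 higher, CSF1R at 0.55. Adjusted over the list alone, the higher and lower counts of these 20 lists differed by at most 1 each from those above.

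With an estimated correlation, camera called 0 of the 132 pairs of list and contrast against 45 with the preset one. At an unadjusted p under 0.05 it gave 5, and fry, which does not compare a list with other genes, called 29. The call of the ribosomal proteins was lost without colony 2 replicate 1 (median −0.03, adjusted p = 0.129) and without control replicate 2 (−0.05, adjusted p = 0.0840), that of oxidative phosphorylation with colony 2 left out (−0.05, adjusted p = 0.389), that of fibroblast markers without control replicate 1 (adjusted p = 0.0553), with a 10 CPM filter (0.0791) or with trends in length and GC removed (0.0526), and that of luminal markers with no filter on low values (21 genes, median −0.098, adjusted p = 0.0529). That of the helicases was lost without control replicate 1 (adjusted p = 0.134), colony 1 replicate 2 (0.119), colony 2 replicate 1 (0.0525) or colony 2 replicate 2 (0.0531), and with median centring (0.0899), a 10 CPM filter (0.0808), a pseudocount of 0.1 (0.0504) or trends in length and GC removed (0.0589). Without carriers of the 7-base sequences tied to the changes, the calls of YAP/TAZ targets (4 genes left, median −0.085, adjusted p = 0.320), R-loop factors (17 left, 0.21, adjusted p = 0.0539) and fibroblast markers (4 left, −0.47, adjusted p = 0.182) were lost, and likewise in each colony. The chaperones gained a call without control replicate 1 (adjusted p = 0.0366), colony 1 replicate 1 (0.0199) or colony 2 replicate 1 (0.0282), and with median centring (0.0449) or no filter (0.0431). NF-kB genes gained a call without colony 1 replicate 2 (adjusted p = 0.0421), and NRF2 (0.0275) and matrix genes (0.0113) without carriers of the 7-base sequences. Without control replicate 2, the calls of PDGFRB (0.15, adjusted p = 0.535), RPS15A (−0.28, adjusted p = 0.222), GINS1 (−0.18, adjusted p = 0.290), CSF1R (0.37, adjusted p = 0.187), CDH1 (0.53, adjusted p = 0.120), IL24 (−0.52, adjusted p = 0.120), TP63 (0.74, adjusted p = 0.0554) and RPLP1 (0.18, adjusted p = 0.0554) were lost. Without control replicate 1, those of ZIC2 (0.32, adjusted p = 0.245), BTG2 (−0.53, adjusted p = 0.172) and NDUFB5 (0.21, adjusted p = 0.135) were.

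**Figure D2:**
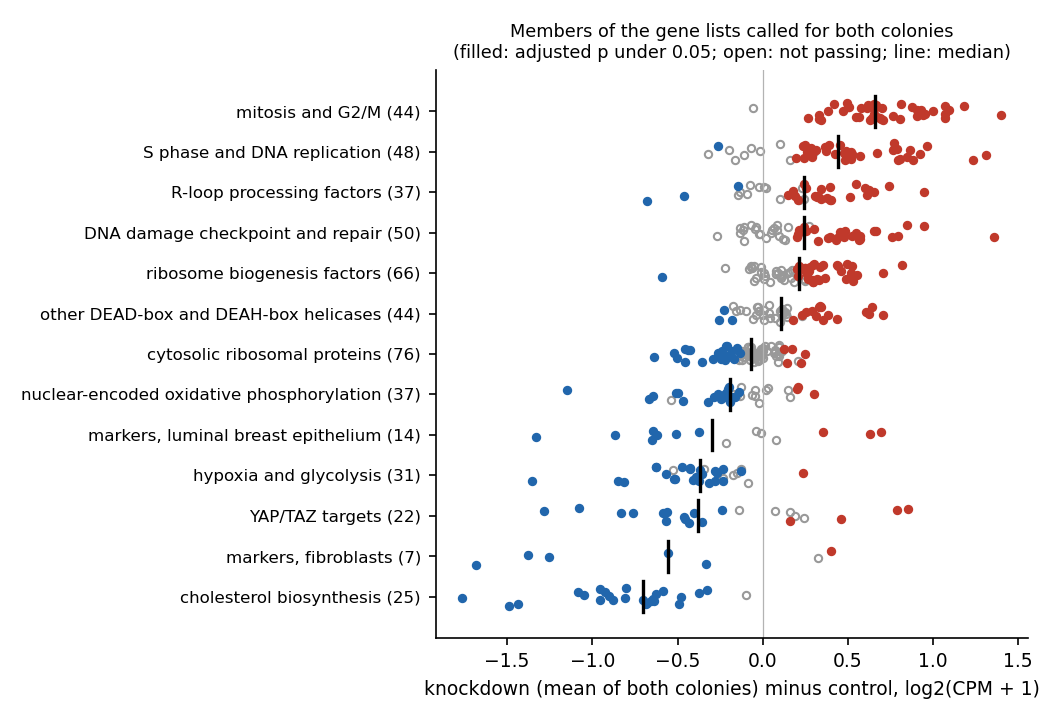
Log2 change of both colonies against control for each tested member of the 13 lists that camera called, with filled points for members past adjusted p under 0.05, open points for the others and a line at each median. The medians ran from 0.66 for mitosis genes to −0.70 for cholesterol genes.

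How far the colonies shared these changes was asked by comparing their calls against control. LMNB1, PRDM8 and SLC7A11 were the 3 largest rises of each colony, and CPA4, AQP3 and VIPR1 were among the largest falls of each, among genes of at least 20 CPM in the higher group. There were 2241 genes higher in both and 1938 lower in both, while 15 went opposite ways. Lists drawn independently would share 589 and 496 genes. Simulated colonies without any change, set against 2 shared simulated controls, had a median of 0 shared genes by limma in each direction, at most 2. Without true changes almost nothing is called, so this count cannot show how far shared controls raise the overlap. Across genes, which are not independent replicates, the log2 changes had a Pearson r of 0.886 (simulated median 0.502) and a Spearman rho of 0.856 (0.467). Their covariance was 0.171, against a simulated 0.0126, a difference of 0.159, and 83.9% of genes had the same sign, against 66.7%. The controls could not be split with 2 libraries in each part, so part of the excess over independent lists may come from the shared controls.

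**Figure D3:**
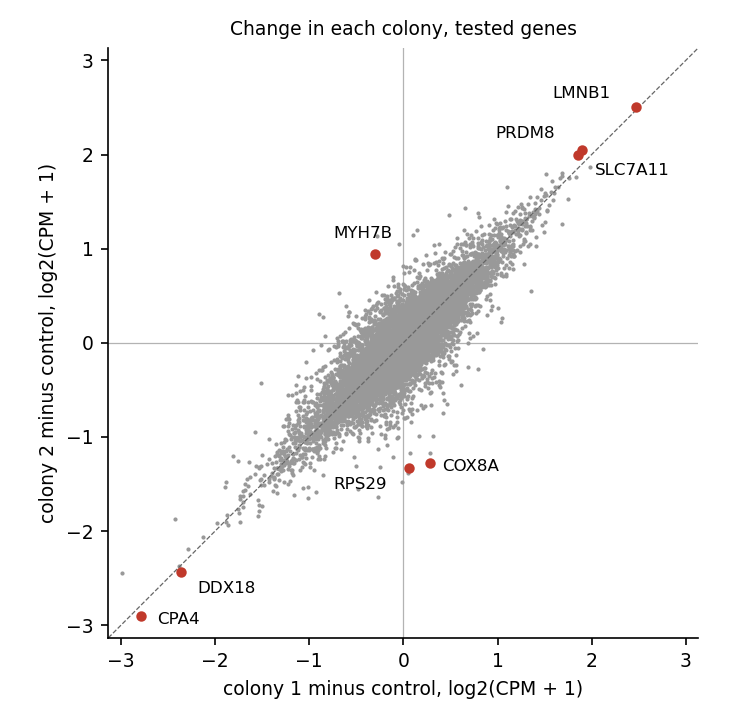
Log2 change against control in colony 1 (x axis) and colony 2 (y axis), with 1 point per tested gene, some named genes in red and a dashed line where the colonies are equal. Pearson's r across genes was 0.886, and DDX18 lay at −2.36 and −2.44.

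Colony 1 against control asked what changed in that colony. Most mitosis and replication genes rose and most genes of the cholesterol list and of the hypoxia and glycolysis list fell. LMNB1 rose by a log2 change of 2.47 (adjusted p = 4.5e-18), from 27.3 ± 0.391 to 156 ± 3.64 CPM (SD, n = 2). PRDM8 changed by 1.90, SLC7A11 by 1.85, TMED5 by 1.84 and HS2ST1 by 1.76. CPA4 had a log2 change of −2.79 (adjusted p = 7.5e-19), from 364 ± 8.19 to 51.9 ± 4.11 CPM, AQP3 one of −2.28, VIPR1 of −1.98 and COL4A6 of −1.89. The limma test called 2881 genes higher and 2500 lower, of which 211 and 260 had an absolute log2 change of at least 1.

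In colony 1, 43 of 44 mitosis genes were higher, as adjusted over the list alone, with a median of 0.70 (camera adjusted p = 3.3e-25, adjusted p = 0.81 with an estimated correlation). S phase genes were higher for 36 of 48, and for 38 adjusted over the list alone, with a median of 0.45 (adjusted p = 1.6e-10, adjusted p = 0.81 with an estimated correlation). Cholesterol genes were lower for 21 of 25, and for 22 adjusted over the list alone, with a median of −0.67 (adjusted p = 1.6e-14, adjusted p = 0.61 with an estimated correlation). Hypoxia and glycolysis genes were lower for 20 of 31, and 21 adjusted over the list alone, with a median of −0.31 (adjusted p = 4.5e-08, adjusted p = 0.81 with an estimated correlation). Ribosome biogenesis factors had 35 of 66 higher and 1 lower, also adjusted over the list alone, with a median of 0.27 (adjusted p = 2.2e-05, adjusted p = 0.84 with an estimated correlation).

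DNA damage genes had 22 of 50 higher, 23 adjusted over the list alone, with a median of 0.25 (adjusted p = 4.7e-04, adjusted p = 0.81 with an estimated correlation). R-loop factors had 21 of 37 higher and 2 lower, 22 and 3 adjusted over the list alone, with a median of 0.31 (adjusted p = 1.6e-03, adjusted p = 0.81 with an estimated correlation). The helicases had 16 of 44 higher and 1 lower, with a median of 0.11 (adjusted p = 0.011, adjusted p = 0.82 with an estimated correlation). YAP/TAZ targets had 13 of 22 lower and 3 higher, with a median of −0.39 (adjusted p = 1.6e-03, adjusted p = 0.81 with an estimated correlation). Luminal markers had 7 of 14 lower and 2 higher, with a median of −0.26 (adjusted p = 0.024, adjusted p = 0.81 with an estimated correlation), and fibroblast markers 3 of 7 lower, with a median of −0.36 (adjusted p = 0.044, adjusted p = 0.81 with an estimated correlation). Adjusted over the list alone, the counts of these last 4 lists were the same, with 3 luminal markers higher. The ribosomal proteins, with 12 of 76 higher and 4 lower, had a median of 0.05 and no camera call (adjusted p = 0.43), which median centring of the libraries brought to −0.0015. Without colony 1 replicate 2 the helicases lost their call (adjusted p = 0.0784), as did fibroblast markers without control replicate 1 (adjusted p = 0.0711), with median centring (0.0600), a 10 CPM filter (0.0791) or trends removed (0.0646), and luminal markers with no filter (median −0.061, adjusted p = 0.0796).

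Colony 2 against control asked the same of the other colony. Most mitosis and replication genes rose here too, most genes of the cholesterol list and of the hypoxia and glycolysis list fell, and 39 of 76 ribosomal protein and 22 of 37 oxidative phosphorylation genes fell. LMNB1 rose by a log2 change of 2.51 (adjusted p = 3.2e-18), from 27.3 ± 0.391 to 160 ± 9.95 CPM (SD, n = 2), PRDM8 by 2.05, SLC7A11 by 2.00, STARD3NL by 1.80 and TTPAL by 1.77. CPA4 had a log2 change of −2.90 (adjusted p = 2.9e-19), from 364 ± 8.19 to 48.1 ± 3.46 CPM, AQP3 one of −2.19, VIPR1 of −1.92 and HSPB8 of −1.91. With limma, 2798 genes were higher and 2714 lower, of which 240 and 246 had an absolute log2 change of at least 1.

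Mitosis genes of colony 2 were higher for 43 of 44, and 43 higher and 1 lower adjusted over the list alone, with a median of 0.66 (camera adjusted p = 2.1e-23, adjusted p = 0.81 with an estimated correlation). Cholesterol genes were lower for 24 of 25, with a median of −0.78 (adjusted p = 3.8e-16, adjusted p = 0.61 with an estimated correlation). Hypoxia and glycolysis genes were lower for 24 of 31, 26 adjusted over the list alone, with a median of −0.40 (adjusted p = 9.5e-10, adjusted p = 0.81 with an estimated correlation). S phase genes had 31 of 48 higher and 1 lower, 34 and 2 adjusted over the list alone, with a median of 0.41 (adjusted p = 8.6e-08, adjusted p = 0.81 with an estimated correlation). The ribosomal proteins had 39 of 76 lower and 4 higher, 40 and 4 adjusted over the list alone, with a median of −0.17 (adjusted p = 1.7e-07, adjusted p = 0.81 with an estimated correlation). Oxidative phosphorylation genes had 22 of 37 lower and 1 higher, 23 and 2 adjusted over the list alone, with a median of −0.29 (adjusted p = 8.2e-06, adjusted p = 0.81 with an estimated correlation).

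DNA damage genes of colony 2 had 24 of 50 higher, also adjusted over the list alone, with a median of 0.23 (adjusted p = 1.7e-04, adjusted p = 0.81 with an estimated correlation). R-loop factors had 21 of 37 higher and 2 lower, with a median of 0.22 (adjusted p = 2.2e-03, adjusted p = 0.81 with an estimated correlation). Ribosome biogenesis factors had 20 of 66 higher and 1 lower, with a median of 0.17 (adjusted p = 8.0e-03, adjusted p = 0.84 with an estimated correlation). Luminal markers had 7 of 14 lower and 1 higher, with a median of −0.33 (adjusted p = 0.013, adjusted p = 0.81 with an estimated correlation). YAP/TAZ targets had 13 of 22 lower and 5 higher, with a median of −0.38 (adjusted p = 0.024, adjusted p = 0.81 with an estimated correlation). Fibroblast markers had 5 of 7 lower, with a median of −0.75 (adjusted p = 0.024, adjusted p = 0.81 with an estimated correlation). Endoplasmic reticulum chaperones had 8 of 21 lower and 3 higher, with a median of −0.22 (adjusted p = 0.036, adjusted p = 0.84 with an estimated correlation). Adjusted over the list alone, the cholesterol, R-loop, ribosome biogenesis and YAP/TAZ counts were the same, while 3 luminal markers and 1 fibroblast marker were higher and 9 chaperones lower. The ribosome biogenesis call was lost without colony 2 replicate 2 (adjusted p = 0.153) or control replicate 1 (adjusted p = 0.175), and the chaperone call without colony 2 replicate 2 (adjusted p = 0.0669) or control replicate 2 (adjusted p = 0.0544). With a 10 CPM filter the chaperones (adjusted p = 0.0569), YAP/TAZ targets (0.0737) and fibroblast markers (0.0776) lost their calls.

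Colony 2 against colony 1 asked how the colonies differed, with DDX18 near the same level in each. Of the mRNAs for ribosomal proteins 36 of 76 were lower in colony 2, as were 8 of 37 for oxidative phosphorylation. COX8A, a subunit of complex IV, held 36.9 ± 1.74 CPM in colony 1 and 12.04 ± 2.39 in colony 2 (SD, n = 2), beside 30.2 ± 1.01 in control. RPS29, a protein of the small ribosomal subunit, held 156 ± 19.8 and 59.4 ± 11.99 CPM, beside 149 ± 2.01 in control. MT-TS1, annotated as a mitochondrial serine tRNA, was higher in colony 2, at 550 ± 6.96 CPM against 321 ± 37.7 in colony 1 and 203 ± 20.7 in control. Polyadenylated RNA was copied and the handling of strand is not given. Whether these reads came from the tRNA itself was not tested.

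Between the colonies, limma called 86 genes higher and 226 lower in colony 2, 2.28% of those tested. Of these, 8 and 17 had an absolute log2 change of at least 1. With the named genes of each library rescaled to the same sum, 122 were higher and 166 lower, so that the higher share of calls went from 27.6% to 42.4%. The largest falls were COX8A at −1.55 (adjusted p = 1.1e-07), NME1, a nucleoside diphosphate kinase, at −1.46 (adjusted p = 6.3e-06), HSPE1, a mitochondrial co-chaperone, at −1.46 (adjusted p = 2.3e-05), RPS29 at −1.38 (adjusted p = 1.2e-05) and ATP5MF of the ATP synthase at −1.37 (adjusted p = 2.4e-07). The largest rises were MYH7B, a myosin heavy chain, at 1.24 (adjusted p = 2.9e-05), SLC25A5-AS1 at 0.88 (adjusted p = 3.0e-06), MT-TS1 at 0.78 (adjusted p = 9.8e-07), ZBED6 at 0.75 (adjusted p = 8.6e-04) and the pseudogene PPIAP22 at 0.71 (adjusted p = 4.8e-04). ZBED6 lies within ZC3H11A, ATP5MF overlaps ATP5MF-PTCD1, SLC25A5-AS1, MYH7B, HSPE1 and RPS29 overlap other genes on the opposite strand, and PPIAP22 resembles its parent gene, so reads could have been split between them.

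The ribosomal proteins had 36 of 76 lower and 1 higher in colony 2, 53 and 2 adjusted over the list alone, with a median of −0.23 (camera adjusted p = 5.4e-39, adjusted p = 0.61 with an estimated correlation). Oxidative phosphorylation genes had 8 of 37 lower, 20 adjusted over the list alone, with a median of −0.23 (adjusted p = 1.0e-14, adjusted p = 0.61 with an estimated correlation). Splicing factors had 2 of 44 lower, 3 adjusted over the list alone, with a median of −0.10 (adjusted p = 1.2e-04, adjusted p = 0.81 with an estimated correlation). Ribosome biogenesis factors had 2 of 66 lower, 5 adjusted over the list alone, with a median of −0.08 (adjusted p = 1.8e-03, adjusted p = 0.84 with an estimated correlation). The helicases had 1 of 44 lower, as adjusted over the list alone, with a median of −0.08 (adjusted p = 7.8e-03, adjusted p = 0.81 with an estimated correlation). Mitochondrially encoded mRNAs had 3 of 13 lower, 5 adjusted over the list alone, with a median of −0.04 (adjusted p = 0.011, adjusted p = 0.81 with an estimated correlation). Heat shock proteins had 2 of 15 lower, 3 adjusted over the list alone, with a median of −0.04 (adjusted p = 0.028, adjusted p = 0.84 with an estimated correlation). YAP/TAZ targets had 1 of 22 higher, 2 adjusted over the list alone, with a median of 0.03 (adjusted p = 0.024, adjusted p = 0.81 with an estimated correlation). Mitosis genes, S phase genes, cholesterol genes and hypoxia genes had no camera call between the colonies, with adjusted p of 0.37, 0.056, 0.058 and 0.052. Some of these passed with a library left out, mitosis (adjusted p = 0.0214) and S phase (2.98e-04) without colony 1 replicate 1 and likewise without colony 2 replicate 2 (0.0212 and 7.83e-04), S phase also without control replicate 2 (0.0491), and cholesterol (2.02e-03) and hypoxia (1.60e-04) without colony 2 replicate 1 and likewise without colony 1 replicate 2 (8.79e-03 and 5.15e-04). With no filter on low values S phase (adjusted p = 0.0177), cholesterol (0.0151) and hypoxia genes (0.0240) passed, and hypoxia genes also with a pseudocount of 0.1 (0.0472).

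Across 12355 protein-coding genes, which are not independent, the change between the colonies rose with coding length (Spearman's rho 0.251). The median coding length was 474 nt for genes lower in colony 2, 2430 nt for those higher and 1404 nt for all tested. Of the 226 lower genes, 165 stood in none of the lists. Leaving out colony 2 replicate 1 left 21 genes higher and 116 lower, colony 2 replicate 2 37 and 131, and colony 1 replicate 2 46 and 124, while leaving out either control gave 134 higher. The calls of ribosome biogenesis factors (adjusted p = 0.914), helicases (adjusted p = 0.406) and heat shock proteins (adjusted p = 0.349) were lost without colony 1 replicate 2, and those of ribosome biogenesis factors (−0.018, adjusted p = 0.558) and heat shock proteins (adjusted p = 0.169) also without colony 2 replicate 1. Those of mitochondrial mRNAs (adjusted p = 0.405) and YAP/TAZ targets (adjusted p = 0.289) were lost without colony 1 replicate 1, and the latter also without colony 2 replicate 2 (adjusted p = 0.0926). With trends in length and GC removed, the calls of mitochondrial mRNAs (adjusted p = 0.785), YAP/TAZ targets (0.121) and heat shock proteins (0.0905) were lost, and the last also with a 10 CPM filter (0.0718) or no filter (0.0710). The mitochondrial median turned to 0.06 without colony 1 replicate 1 and to 0.05 with trends in length and GC removed.

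**Figure D4:**
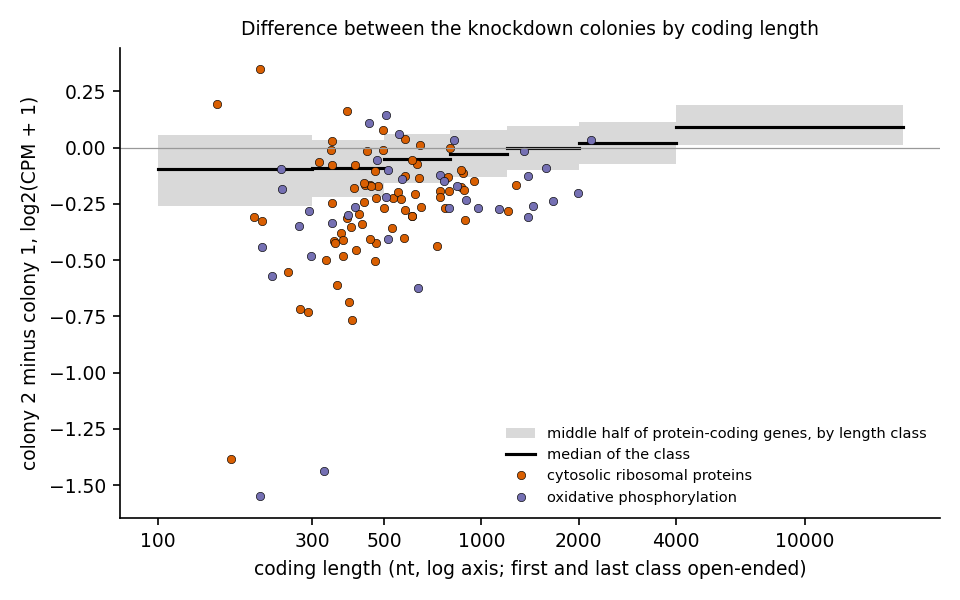
Log2 change of colony 2 against colony 1 by coding length in nt (log axis), with a line at the median and a grey band over the middle 50% of protein-coding genes in each length class, and points for ribosomal protein and oxidative phosphorylation genes. The class median went from −0.10 for the shortest genes to 0.09 for the longest, and most of the points lay below 0.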

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

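The tests over protein-coding genes alone and against genes of like coding length were chosen after the result was seen.

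These results stand out because a test of colony 2 minus colony 1 passed, by limma for genes and by camera for lists, although each colony was compared with the same controls. There were 86 genes higher and 226 lower in colony 2. The median log2 change was −0.23 for ribosomal proteins and −0.23 for oxidative phosphorylation genes. It was −0.10 for splicing factors, −0.083 for ribosome biogenesis factors, −0.084 for the other helicases, −0.042 for mitochondrially encoded mRNAs, −0.039 for heat shock proteins and 0.031 for YAP/TAZ targets. These list values passed camera at the preset correlation, and with an estimated correlation their adjusted p was 0.61 to 0.84. The higher genes were MYH7B at 1.24, SLC25A5-AS1 at 0.88, MT-TS1 at 0.78, ZBED6 at 0.75 and PPIAP22 at 0.71. The lower genes were COX8A at −1.55, NME1 at −1.46, HSPE1 at −1.46, RPS29 at −1.38 and ATP5MF at −1.37.

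Short mRNAs, among them many for ribosomal proteins and the respiratory chain, had lower medians in colony 2 than in colony 1. Outside the lists, genes under 800 nt differed from those of 2000 to 4000 nt by a median of −0.0360, a bound that decides nothing, since 353 of the 545 short genes were not protein coding and had a median of 0.02, against −0.18 for the 192 that were. Over protein-coding genes the difference was −0.155 (−0.203 to −0.113 in the pairings of libraries, against −0.0252 to 0.0160 between replicates), which is consistent with a length trend between the libraries, from library preparation or from the cells. The members of the ribosomal protein and oxidative phosphorylation lists lay further down, by −0.161 (95% interval −0.205 to −0.107) against the genes nearest in coding length and level. Against genes of like transcript length it was −0.158, but these included short noncoding genes, which lay higher, so this value adds no support. The comparison by coding length and level argues against length as their whole cause. The interval resampled the 113 members, which are not independent, so it does not measure the spread between libraries. How near the matched genes came in level was not checked. A lower programme of these genes in colony 2 may therefore add to a length trend, and since the labels name no batch, a colony's biology and its handling stay open.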

How the results depend on the processing

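Chosen after seeing the data were the rescaling of named genes, the removal of length and GC trends, colony 2 left out, and genes without certain 7-base sequences. DDX18 kept its direction and call in every fit, with log2 changes of −2.51 to −2.29 for both colonies, −2.52 to −2.21 for colony 1 and −2.54 to −2.33 for colony 2 on leaving out 1 library, and 16.5% to 20.6% and 16.3% to 18.9% of control left. The level left in colony 2 moved by more than 1 SD without either control. Counts stayed within 1.5 times in 154 cases and moved further in 33. Of the list results, 2077 kept direction and call, 119 lost the call, 56 gained it and 1 reversed, and for named genes 1927 were kept, 27 lost and 2 reversed. Where no other cause is given, the cause was not tested. An absolute log2 change of at least 1, a stricter threshold, left 210 higher and 228 lower for both colonies, 211 and 260 for colony 1, 240 and 246 for colony 2 and 8 and 17 between colonies. Median centring left a median change of −0.04 in each comparison with control. It turned the balance to 2675 higher and 3511 lower for both colonies, 2356 and 3016 for colony 1 and 2403 and 3176 for colony 2. Without carriers of the 7-base sequences 5289 genes were tested, which left, in the same order, 1083 and 1088, 1020 and 846, 901 and 1047, and 26 and 122, with 746 and 662 shared. Between colonies, 130 genes were higher with only those groups fitted, and 57 higher and 146 lower with length and GC trends removed. List calls numbered 0 with an estimated correlation and 29 with fry. With colony 2 left out, RPS29 (0.055, adjusted p = 0.633), COX6A1 (0.048) and the ribosomal protein list (0.04996, adjusted p = 0.409) reversed, since colony 1 alone remained. In that fit RPS15A (−0.18, adjusted p = 0.389), MT-ND6 (−0.149, 0.0546), GINS1 (−0.24, 0.109), BTG2 (−0.62, 0.0605), ZIC2 (0.40, 0.141) and PDGFRB (0.37, 0.0913) lost their limma calls.

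Leaving out 1 library, with the lone library assumed to vary like the others, gave 2518 to 3068 higher and 2233 to 2891 lower genes for both colonies, 2082 to 2815 and 1870 to 2506 for colony 1, 2063 to 2831 and 1849 to 2788 for colony 2, and 21 to 134 and 116 to 318 between colonies. Shared genes were 1759 to 1990 higher and 1448 to 1738 lower, and list calls 42 to 51. Deviations of libraries with the same number correlated at 0.119, 0.128 and 0.159, but each comparison has only 2 such pairs and the labels state no pairing. With the replicate block, 3642 and 3428 genes were called for both colonies, 3377 and 3021 for colony 1, 3310 and 3260 for colony 2, and 361 and 675 between colonies, and the chaperones against control and the hypoxia and MYC lists between colonies gained calls. Not run, because the deposited values were CPM, were edgeR's quasi-likelihood test, DESeq2's Wald test, calls, levels and size factors, and limma-voom. For both colonies against control, simulated changes of 1.5-fold were recovered for 9 of 24 genes under 10 CPM and 44 of 44 above. In that setting small changes of weakly expressed genes were thus often missed. The simulation changed far fewer genes than the 44.7% called in the data and gave every gene 1 common extra variance. Recovery depends on both, so it may differ in the data.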

Other observations

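The test of windows in the DDX18 mRNA and the counts of genes without certain sequences were chosen after the result was seen.

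Carriers of some short sequences in the 3′ untranslated region were shifted on average against other genes in both colonies, though most carriers were not called in that direction. Among 15811 sequences of 7 bases in 12136 genes, with region length, GC and level adjusted, 13 were tied to higher and 6 to lower expression beyond 100 permutations. The strongest was GTAAGCA, whose 960 carriers, LMNB1 and SLC7A11 among them, were shifted by 0.23. Of its carriers 44.1% were called higher and 12.9% lower, against 22.6% and 23.5% of the other genes, and it stood in 62 of the 189 higher genes with a log2 change of at least 1. TGTAAGC and AGTAAGC, which share GTAAGC with GTAAGCA, came next in strength, with carriers shifted by 0.17 and 0.18. Lower in rank, AGTACTT and GAGTACT carriers were shifted by 0.11 and 0.12. Many of the higher sequences overlap one another, so they are not separate signals. The lower sequences were CTTGGCA, CCTTGGC, CTTGGCT, TAAGTGA, ATTAAGT and TATTAAG, with shifts of −0.0845 to −0.0711. Carriers of any of these were called lower in 26.3% and higher in 24.0% of cases, near the 22.6% and 24.3% of all genes searched. In colony 1 the strongest shift was 0.235 and in colony 2 it was 0.233. Between the colonies, 0 sequences that passed reached a shift of 0.1, while 5 passed with smaller shifts.

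The changes shared by the colonies exceeded what the spread within groups gives through shared controls, with a covariance of 0.171 against at most 0.0131 in simulation. A difference common to both control libraries was not simulated and stays open as a source. There were 8 passing sequences with a shift of at least 0.1, all tied to higher expression (highest |z| 15.5, against 5.27 in permutations). Small RNAs acting through seed matches in the control cells could give this. The lower sequences, at −0.0845 to −0.0711, did not reach that bound, so small RNAs in the knockdown cells did not meet it and stay open. A common hairpin against firefly luciferase, CTTACGCTGAGTACTTCGA, holds 2 of the 13 higher sequences on the strand as written. These are AGTACTT and GAGTACT, which overlap each other. The test of this hairpin was built on GTAAGC, a core of the strongest sequences of these same data. No other hairpin was searched for comparison. The reverse complement of these 19 bases holds none of the 13. GTAAGCA, the strongest, thus stands on neither strand. Bases beyond the 19 were not searched, so this does not decide whether the hairpin was present. The further test of this hairpin, on CGTAAGC carriers, gave 0.0196 with a larger SE of 0.0367. Its presence in the control cells thus cannot be told apart from its absence. The DDX18 mRNA holds CCAAGGTTCCATTAAGTGA in its coding region, across chromosome 2 117826378 to 117826382 and 117828949 to 117828962. The window sought was 17 to 23 bases from CCAAGG to TAAGTGA, built from the lower sequences of these same data. It stood in 0.0439% of other tested genes. The DDX18 window holds TAAGTGA and ATTAAGT, but CTTGGCA, CCTTGGC, CTTGGCT and TATTAAG stand on neither of its strands. A hairpin against it may have been used in both colonies, although the labels' descriptions number the colonies KD1 and KD3, which leaves different hairpins open. The labels name no construct, and among the 5289 genes with none of the 8 higher sequences with a shift of at least 0.1 and none of the 6 lower ones, 1118 were still called higher and 1117 lower, so low DDX18 stays open as a source of those changes, untested apart from the colonies themselves.

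Most mitosis genes rose and most cholesterol genes fell in both colonies. With trends in transcript length and GC removed, their medians were 0.62 and −0.69, which argues against such trends as the cause. The median was 0.65 for the 34 mitosis genes without the 8 higher sequences with a shift of at least 0.1 and −0.68 for the 14 cholesterol genes without the 6 lower ones, which argues against direct matches to these sequences. A response to low DDX18, to the selection of colonies, or an indirect effect of small RNAs may underlie them. No library was labelled as a rescue, and the labels do not say whether the colonies carry different hairpins.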
